A study of Harpegnathos saltator with 47 samples.

How the data were processed

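Brains without optic lobes of Harpegnathos saltator were dissected, and RNA was extracted with TRIzol and treated with DNase, per the labels' protocols. Libraries were made from polyA RNA with random hexamers, and dUTP in the second strand kept the strand, per the labels' protocols. The submitters' processing notes name STAR 2.5.0b and DESeq2, the latter with no version. The genome build, the annotation and the counting settings are not given in the sources used here.

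The authors deposited RPKM values for 33 ants and 19198 rows, of which 18429 are genes and the rest rows of rRNA (43), tRNA (542), snRNA (33) and miRNA (151). The labels list 47 sequencing runs, and the deposited RPKM table has 1 column per ant although 14 ants have 2 runs. Whether the value of such an ant comes from 1 run or from both is not given in the sources used here. The number of further per-sample columns was 0. The authors' deposited table for gamergates against transition workers gives, per the file headers, a mean signal (baseMean), a log2 fold change of workers over gamergates, a p-value and an adjusted p-value. The authors used DESeq2 for this table, per the submitters' processing notes, and the sign of its log2 fold change was turned around here so that positive values mean higher in gamergates. The mean signal in the authors' deposited table is not that of the reads recovered here: over 9725 genes with at least 10 normalized reads, its ratio to the mean of recovered reads in the same 23 ants, after median-ratio scaling, had a median of 1.19 and ran from 0.982 at the 5th to 1.65 at the 95th percentile. The counts behind the authors' test and behind the deposited RPKM values were thus not shown to be the same.

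The RPKM values of each gene were whole multiples of what 1 read is worth in each ant. Relative depths were found from rows seen in few ants, and whole reads were recovered for all 15320 rows above 0 in at least 2 ants. Of 404997 values, 100% came out whole within 0.01 reads. The recovered depths differed from the sums of recovered reads in genes by at most 0.000984%, so the depth in the deposited RPKM values is of reads in genes without the rRNA, tRNA, snRNA and miRNA rows. Depth ran from 3904943 to 11159675 reads in genes per ant, with means of 5405981 in batch A, 6759599 in batch B and 8621756 in batch C. Correlations between ants on the log2 scale ran from 0.901 to 0.989, and no 2 ants had near-identical columns.

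Groups were taken from the caste and colony labels, as 12 gamergates and 11 workers of transition nests and 10 workers of stable colonies. Each replicate number is read as 1 ant. The labels do not say which ants shared a nest, so p-values measure the spread between these samples. The labels mark the ants of all 3 groups with day 120. The age of the ants from stable colonies is not given separately from the protocol for transition nests. Sequencing batches come from the run dates in the library names. Batch A held 2 gamergates and 2 transition workers and no stable workers, batch B held 5 ants of each group, and batch C held 5 gamergates, 4 transition workers and 5 stable workers. The library names also start with b, H or ND, and the meaning of these prefixes is not given. The prefix b stood on 11 of 12 gamergates, 3 of 11 transition workers and 0 of 10 stable workers.

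The design was fixed before the data were examined. Values were tested on the log2(RPKM + 1) scale with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend), with all 3 groups in one model and the batch as a term. Rows with a mean of at least 0.5 RPKM over all ants were tested, 11234 in number, of which 11145 were genes. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Sets of rRNA, tRNA, snRNA and miRNA rows were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one. These sets were chosen after the files had been seen, and adjustment was over the 4 sets and 3 comparisons together. Of the 3 kinds of row other than rRNA, snRNA had an adjusted p of 0.0321 between gamergates and stable workers with the preset correlation and an adjusted p of 0.937 with the estimated one, and no tRNA or miRNA set passed in any comparison.

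On simulated data with the real means, spreads and design and 11234 genes, 50 genes were changed at each of 4 sizes. For gamergates against transition workers 66% of genes changed 1.5-fold, 88% of those changed 2-fold and 98% of those changed 3-fold were recovered. For transition against stable workers the shares were 60%, 78% and 98%, and for gamergates against stable workers 56%, 84% and 100%. The simulation draws genes independently and with a normal spread, and the changed genes of all 4 sizes enter the same adjustment. The shares describe that setting. Where fewer genes pass, as in the comparisons reported here, the adjustment is stricter and recovery is lower.

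The rule for named genes took those past the threshold with the same sign within batches B and C and with a known name, then members of gene lists, corazonin and vitellogenin. The files do not pair their IDs with names, and 0 of the 11234 tested IDs matched the 14329 genes of the reference gene table. The part of the rule on names could therefore not be applied. The rule also set a larger number of genes in each direction, for each pair of groups. This number was cut after the files were found to hold IDs alone. Named instead are the 2 IDs with the highest and the 2 with the lowest log2 fold change between gamergates and transition workers. They passed the threshold with the same sign within batches B and C. The 1 gene called between the worker groups is named as well, and none was named for gamergates against stable workers. The gene lists, corazonin and vitellogenin are not analysed here.

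Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 5 RPKM, median-ratio and quantile scaling, no batch term, the replicate number as a block, the library name prefix as a further term, only the 2 groups compared, each of batches B and C alone, no batch A, array weights and no variance trend. Alternatives chosen after seeing the data were limma's voom on the recovered reads, the share of rRNA reads as a further term, the non-coding rows left out, transition workers 9 and 10 left out together, and each ant left out in turn. Random splits of the ants were drawn 100 times within batches for each comparison. Overlaps between comparisons that share gamergates were set beside 100 simulations in which residuals of whole ants were shuffled within batches. Shares of rRNA reads and depths were compared with 20000 permutations within batches. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the recovery of reads, the closing tests and the plots.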

Results

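Brains without their optic lobes were profiled by strand-specific RNA sequencing of polyA RNA in the ponerine ant Harpegnathos saltator. In this species workers that win dueling contests after the loss of the reproductive can become gamergates, which are mated workers that lay eggs. The gamergates and transition workers were taken 120 days after young ants had been moved to nests without a dominant reproductive. There were 12 gamergates and 11 workers from such transition nests, and 10 workers labelled as coming from stable colonies. The labels mark these 10 with day 120 as well. The 47 sequencing runs of the series came from these 33 ants, 14 of which had 2 technical runs. The deposited table has a single value per gene and ant, as RPKM, which scales reads by gene length and library depth. Whole reads could be recovered from it, and the libraries held 3904943 to 11159675 reads in genes. The mean was 7933626 ± 2245546 reads (SD, n = 12) in gamergates, 6270847 ± 1713095 (SD, n = 11) in transition workers and 7953966 ± 1816077 (SD, n = 10) in stable workers. The difference in depth between gamergates and transition workers had an adjusted p of 0.163 over 6 comparisons in a two-sided permutation test within sequencing batches. The files give gene IDs without gene names, so the genes below are named by ID, and the position of each is not given in the sources used here.

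The comparison of gamergates with workers from transition nests asks which brain transcripts differ between reproductive and non-reproductive ants under the same kind of nest. The largest difference among called genes lay in Hsal_10714, whose mean was 81.5 ± 149 RPKM (SD, n = 12) in gamergates and 0.288 ± 0.289 RPKM (SD, n = 11) in transition workers. The median in gamergates was 35.5 RPKM, and without gamergate 10 their mean was 41.2 ± 53.0 RPKM (SD, n = 11). The level exceeded the highest transition worker in 9 of the 12 gamergates, and its values in gamergates ran from 0 to 525 RPKM. Hsal_04952 was also higher in gamergates, at 121 ± 56.7 RPKM (SD, n = 12) against 45.1 ± 15.0 RPKM (SD, n = 11). In the other direction, Hsal_05445 averaged 87.0 ± 76.5 RPKM (SD, n = 12) in gamergates and 335 ± 141 RPKM (SD, n = 11) in transition workers. Hsal_09095.2 averaged 11.1 ± 12.3 RPKM (SD, n = 12) in gamergates and 40.2 ± 17.1 RPKM (SD, n = 11) in transition workers, and 10 of the 12 gamergates lay below the lowest transition worker.

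On the log2(RPKM + 1) scale, which understates the change of low genes, the difference between gamergates and transition workers was 3.85 (SE 0.750) for Hsal_10714, with a Benjamini-Hochberg adjusted p of 0.0246 in limma. For Hsal_04952 it was 1.29 (SE 0.240), with an adjusted p of 0.0246 in limma. Hsal_05445 had a difference of -2.29 (SE 0.356) and Hsal_09095.2 one of -2.01 (SE 0.325), each with an adjusted p of 0.00355 in limma. The calls of Hsal_10714 and Hsal_04952 were each lost in 8 of 19 settings other than leaving out an ant. Those of Hsal_05445 and Hsal_09095.2 were each lost in 4. These genes were named by a rule that required the same sign within batches B and C, which hold all 3 groups. Within batch B and batch C the differences were 4.20 and 3.77 for Hsal_10714, 1.22 and 1.21 for Hsal_04952, -1.88 and -2.02 for Hsal_05445, and -2.25 and -1.19 for Hsal_09095.2.

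**Figure D1:**
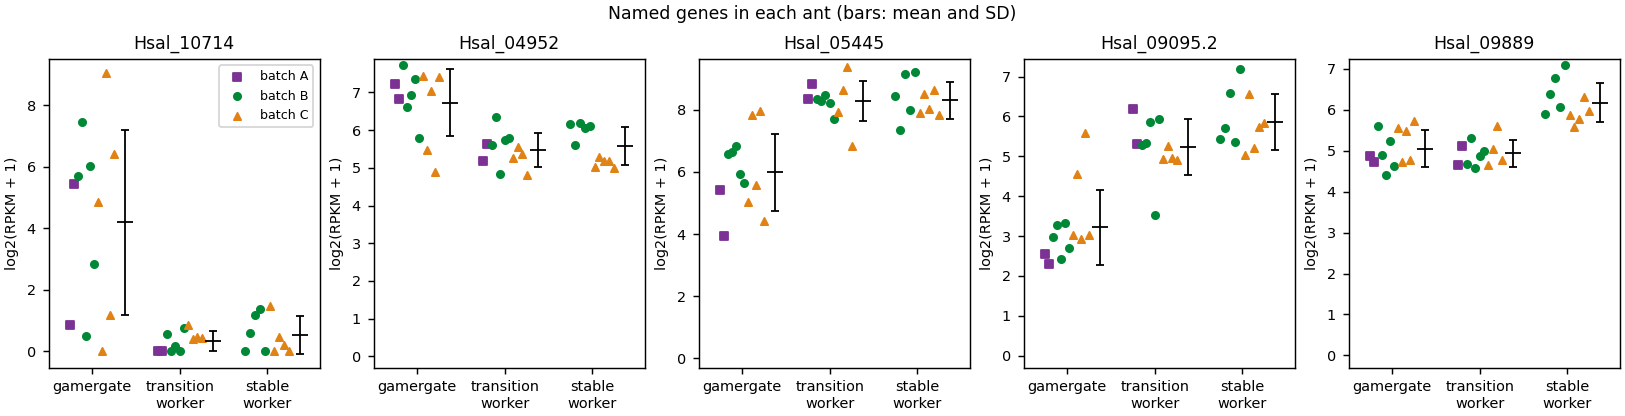
Level of 5 genes in each ant, as log2(RPKM + 1), by group. Each point is 1 ant, its colour and shape give the sequencing batch, and the bars show the mean and SD of each group. Hsal_10714 lies at 1.799 RPKM or less in workers and spreads from 0 to 525 RPKM in gamergates, and Hsal_09889 is higher in stable workers than in both groups from transition nests.

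In all, 12 of 11234 tested rows passed an adjusted p of 0.05 in limma between gamergates and transition workers, 6 higher and 6 lower in gamergates. With quantile normalization the split was 12 higher and 5 lower. On the log2(RPKM + 1) scale, the 6 genes that rose did so by 1.51-fold to 14.4-fold, and the 6 that fell were 1.57-fold to 4.88-fold higher in transition workers. At an unadjusted p under 0.05 there were 1055 genes. With the replicate number as a block 2 genes were called. No gene was called when the prefix of the submitters' library names, which partly coincides with the groups, entered the model as a further term, nor without the 4 ants of batch A. Leaving out single ants gave from 2 genes, without gamergate 6, gamergate 12 or transition worker 1, to 37 genes, without transition worker 10.

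The same pair of groups is compared in the authors' deposited table, which lists 68 genes with an adjusted p under 0.05, 32 higher in gamergates and 36 higher in transition workers. Of these, 67 were tested here, and all 67 had the same sign in both sources. Both sources called 9 genes, and 63 of the 67 had an unadjusted p under 0.05 in limma here. These 67 genes were chosen by their difference between the same groups in the authors' deposited table. Their shared sign and low p-values here are thus not independent support. Across genes, which are not independent replicates, the fold changes of both sources had a Pearson correlation of 0.887 and a Spearman correlation of 0.942. The mean signal in the authors' deposited table differed from the mean of the reads recovered here by a median ratio of 1.19 that varied between genes, so the counts behind both sources were not shown to be the same. In the authors' deposited table the log2 fold change of gamergates over transition workers was 5.09 for Hsal_10714, 1.34 for Hsal_04952, -1.81 for Hsal_05445 and -1.64 for Hsal_09095.2. Without transition worker 10 the calls made by both sources numbered 19, and without gamergate 6, gamergate 12 or transition worker 1 they numbered 2.

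**Figure D2:**
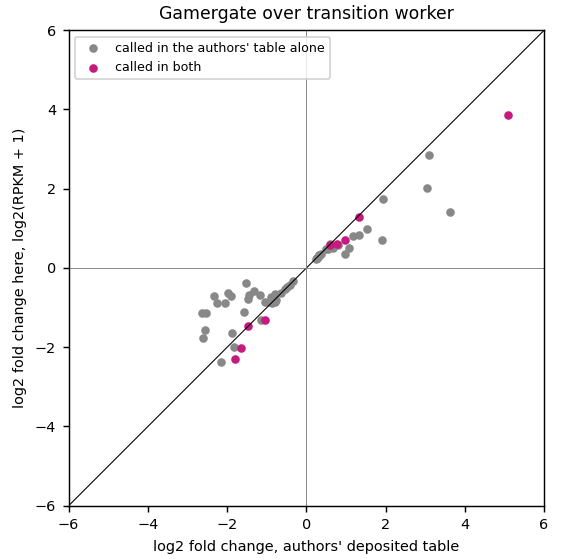
Log2 fold changes of gamergates over transition workers for the 67 genes called in the authors' deposited table and tested here. The horizontal axis gives the value in the authors' deposited table and the vertical axis the value on the log2(RPKM + 1) scale. Points are genes, the 9 coloured ones were called in both sources, and the diagonal marks equal values. All 67 genes lie on the same side of 0 in both.

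Workers from transition nests and workers from stable colonies share a caste and differ in the kind of colony. A single gene passed an adjusted p of 0.05 in limma between them, Hsal_09889. It averaged 30.2 ± 7.55 RPKM (SD, n = 11) in transition workers and 74.9 ± 27.9 RPKM (SD, n = 10) in stable workers, a difference of -1.21 (SE 0.183) on the log2(RPKM + 1) scale with an adjusted p of 0.00228 in limma. Of the 11 transition workers, 10 lay below the lowest stable worker. Gamergates from transition nests had 33.6 ± 10.9 RPKM (SD, n = 12) of it, also below stable workers by -1.09 (SE 0.179, adjusted p = 0.00474 in limma). Between gamergates and transition workers it differed by 0.12 (95% confidence interval -0.23 to 0.47). Within batch B the difference between transition and stable workers was -1.55, and within batch C it was -0.89. The call was lost with the library name prefix as a further term, at a difference of -1.06 and an adjusted p of 0.0775 in limma, and also with the replicate block and within batch B or batch C alone, 4 of 19 settings other than leaving out an ant. The adjusted p over all alternatives ran from 0.00051 to 0.899.

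The 4 genes named above for gamergates and transition workers did not pass the test between the 2 worker groups. The difference between transition and stable workers was -0.05 for Hsal_10714 (95% confidence interval -1.69 to 1.59), -0.17 for Hsal_04952 (-0.70 to 0.35), 0.07 for Hsal_05445 (-0.71 to 0.85) and -0.60 for Hsal_09095.2 (-1.31 to 0.11). At an unadjusted p under 0.05 there were 333 genes, 104 higher and 229 lower in transition workers, which is 2.96% of those tested. The 32 tested rows of ribosomal RNA had a median difference of -0.39, with 7 of them higher in transition workers. As a set they had an adjusted p of 0.00864 in limma's camera with a preset correlation of 0.01, and an adjusted p of 0.937 with an estimated correlation. The estimated correlation was 0.512, far above the preset, so the preset value overstates the evidence for this set. The share of reads from ribosomal RNA had an adjusted p of 0.931 between the worker groups in a two-sided permutation test within batches. No single row of ribosomal RNA was called.

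The comparison of gamergates with workers of stable colonies spans both caste and kind of colony. Hsal_09095.2 averaged 64.3 ± 36.0 RPKM (SD, n = 10) in stable workers, and the difference of gamergates from them was -2.61 (SE 0.341, adjusted p = 0.000112 in limma). Of the 12 gamergates, 11 lay below the lowest stable worker. Hsal_05445 was at 341 ± 146 RPKM (SD, n = 10) in stable workers and differed by -2.22 (SE 0.373, adjusted p = 0.00474 in limma). Hsal_10714 was at 0.573 ± 0.714 RPKM (SD, n = 10) in stable workers and differed by 3.80 (SE 0.786, adjusted p = 0.0307 in limma). Hsal_04952 was at 49.5 ± 17.6 RPKM (SD, n = 10), with a difference of 1.12 (SE 0.252, adjusted p = 0.0475 in limma). This last call was lost without 28 of the 33 ants, left out one at a time, and in 14 of 19 other settings, and that of Hsal_10714 without 12 of the 33 and in 9 of 19.

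Between gamergates and stable workers 26 rows passed an adjusted p of 0.05 in limma, 8 higher and 18 lower in gamergates, and 849 had an unadjusted p under 0.05. The split was 11 higher and 12 lower with quantile normalization, and 5 higher and 6 lower with median-ratio scaling. No gene was called with the library name prefix as a further term, and the count ran from 4 without stable worker 5 to 47 without gamergate 11. With the prefix term the differences were 4.79 for Hsal_10714, 1.73 for Hsal_04952, -2.38 for Hsal_05445 and -2.53 for Hsal_09095.2. That of Hsal_09889 shrank to -0.65. All of these had an adjusted p of 0.55 or more in limma. The 32 rows of ribosomal RNA had a median difference of -0.37. Their adjusted p in limma's camera was 0.00864 with the preset correlation of 0.01 and 0.937 with the estimated correlation of 0.512. The share of reads from ribosomal RNA was 1.26 ± 0.864% (SD, n = 12) in gamergates, 3.12 ± 5.98% (SD, n = 11) in transition workers and 2.21 ± 2.35% (SD, n = 10) in stable workers. The medians were 0.879%, 0.647% and 1.10%, and without transition worker 9 the mean of transition workers was 1.44 ± 2.26% (SD, n = 10). Between gamergates and stable workers these shares had an adjusted p of 0.642 in a two-sided permutation test within batches.

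The 2 comparisons of gamergates with workers had 8 called genes in common, all in the same direction, 3 higher and 5 lower in gamergates. Independent lists of these sizes would share 0.00427 genes higher and 0.00961 genes lower. Both comparisons use the same gamergates. In 100 simulations of unchanged groups no gene was called in both. With unchanged groups few genes are called at all, so this count could hardly come out otherwise. It does not measure the overlap that shared gamergates bring to lists of called genes. The fold changes of both comparisons correlated across genes at 0.672, which lies within the range of the simulations (median 0.421, from -0.0906 to 0.756). Their covariance was 0.0360, against a median of 0.0125 in the simulations. With the gamergates split so that each comparison had its own, the median correlation over 100 splits was 0.342 and the median covariance 0.0224. The number of shared genes fell to 0 with the library name prefix as a further term, and ran from 2, among others without gamergate 2, to 16 without transition worker 10.

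The caste difference could be compared between batch B, with 5 gamergates and 5 transition workers, and batch C, with 5 and 4. No gene had a caste difference that changed between these batches at an adjusted p of 0.05 in limma, and 310 had an unadjusted p under 0.05. On the recovered reads limma's voom also gave 0 genes. Over all tested genes the caste differences of both batches correlated at 0.125 (Pearson) and 0.0587 (Spearman), and 48.9% had the same sign. In batch B alone and in batch C alone 0 genes were called between gamergates and transition workers. With so few ants, the lack of a changed gene does not show that the caste difference was the same in both batches.

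To place each ant on the axis between the castes, the model was fitted without it, and its levels at the 20 genes with the smallest p between gamergates and transition workers were projected so that transition workers of its batch lie at 0 and gamergates at 1. This caste position was 0.949 ± 0.521 (SD, n = 12) in gamergates, 0.136 ± 0.247 (SD, n = 11) in transition workers and 0.0385 ± 0.201 (SD, n = 10) in stable workers. Gamergates 9 and 11 lay at 0.104 and -0.0105, and the other 10 gamergates at 0.520 or more. Transition worker 6 lay at 0.686, and the other 10 transition workers and all 10 stable workers below 0.5. The position depended on the number of genes for some ants. With 10 genes gamergate 5 lay at 0.326 and transition worker 6 at 1.11, and with 200 genes transition workers 6 and 10 lay at 0.714 and 0.667. With 10, 20, 50 or 200 genes gamergate 9 stayed between 0.00806 and 0.104 and gamergate 11 between -0.0105 and 0.0284.

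**Figure D3:**
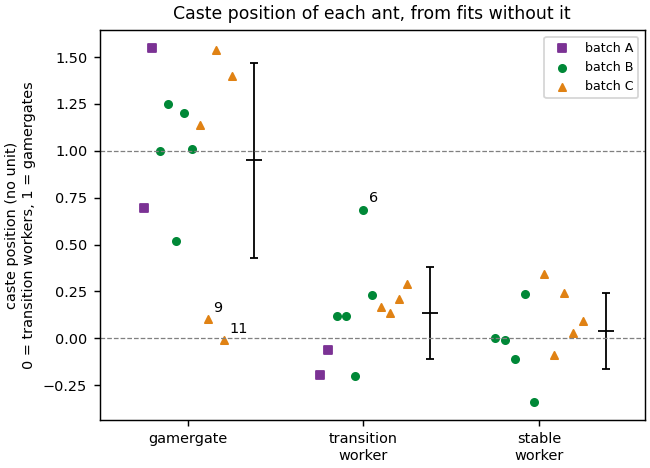
Caste position of each ant, which has no unit, by group. Each point is 1 ant placed by a fit that left it out, colours and shapes give the sequencing batch, bars show the mean and SD, and dashed lines mark the transition workers (0) and the gamergates (1). Gamergates 9 and 11 lie at 0.104 and -0.0105, among the workers, and transition worker 6 lies at 0.686.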

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

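The tests of label exchange and shallow libraries for gamergates 9 and 11 and those on the library name prefix were chosen only after the result was seen. The tests on transition worker 10 and the random splits were fixed before their results were seen. In the group of 10 stable workers, the only one of 4 to 10 ants, 9 measures were examined for a single ant far from the rest, and 0 passed the 95% critical value of Dixon's test.

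Of 100 splits of the gamergates and transition workers within batches, the real one included, 4 gave at least as many genes as the 12 of the real split. This share lies under the 0.05 set beforehand, but too close to it for 100 splits to exclude chance. The highest other splits gave 474 and 95 genes. The split with 474 genes placed 6 gamergates with 6 transition workers, and 6 of its 12 ants in that group had the prefix b, and it also held transition worker 10, which stands apart from the other ants. A split with this many genes points to a structure of the samples, and what it follows was not tested. For transition against stable workers 3 of 100 splits gave at least the 1 gene of the real split, and the highest other split gave 1. For gamergates against stable workers the real split, with 26 genes, was the only 1 of 100 to reach its count, and the highest other gave 0. Both shares lie under 0.05. For the worker groups the count is 1 gene, which other splits also reached, so no conclusion on chance is drawn there. For gamergates against stable workers the splits argue against chance. They cannot tell caste from the library name prefix, as b stood on 11 of 12 gamergates and 0 of 10 stable workers. Batch A held no stable workers, so its gamergates kept their group in every split.

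Gamergates 9 and 11, both of batch C, lay at caste positions of 0.104 and -0.0105. They had 225 and 248 RPKM of Hsal_05445, the highest of the gamergates. Hsal_10714 was listed at 0 RPKM in gamergate 9 and at 1.29 RPKM in gamergate 11, and it was also low in gamergates 1 and 5, at 0.795 and 0.42 RPKM. Shallow libraries are argued against, since the shallower of both lay at -0.333 SD from the median gamergate of batch C in reads. An exchange of labels within batch C needs a worker there at a gamergate position. The highest lay at 0.344 with 20 genes. With 200 genes transition worker 10 lay at 0.667, but with 10 and 50 genes it lay at 0.306 and 0.362. Its 656 RPKM of Hsal_05445, 0.392 RPKM of Hsal_10714 and 30.3 RPKM of Hsal_09095.2 were at worker levels. Because its position with 200 genes goes the other way, an exchange of a single gamergate within batch C stays open. An exchange of both needs a further such worker. With 200 genes the next highest worker of batch C, transition worker 11, lay at 0.460, below 0.5. An exchange across batches cannot be told apart from other causes either, because transition worker 6 of batch B lay at 0.686, with 10.5 RPKM of Hsal_09095.2, below the 28.9 RPKM or more of all other workers and above the 3.93 to 9.06 RPKM of the 10 gamergates other than 9 and 11. Its 299 RPKM of Hsal_05445 and 0 RPKM of Hsal_10714 were at worker levels. A single wrong label and a biological difference between gamergates, such as an incomplete or reversed transition, stay open and untested.

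Transition worker 10 stood apart from the other ants of batch C, with 104 genes over 4-fold higher and 265 over 4-fold lower than their mean. By the same measure transition worker 5 of batch B had 291 genes higher and 29 lower, which was not examined further. The genes high in transition worker 10 had a median log2 shift of 2.43 in it. Its 7.82% of rRNA reads could be thought a cause, but in transition worker 9, with 19.96% of rRNA reads, the same genes shifted by -0.0962, and in stable worker 7, with 7.04%, by -0.0916. Few reads are argued against as well, since transition worker 3, with 3904943 reads against the 4952600 of transition worker 10, had a shift of -0.0686. RNA of another tissue carried along in the dissection stays open, because testing it needs gene names. Of the 36 genes higher in transition workers in the authors' deposited table, 14 were among the 104. Without transition worker 10 a single one of the 67 genes tested here lost over 50% of its fold change on the log2(RPKM + 1) scale. Some of these fold changes were larger in the authors' deposited table, as for Hsal_10448 with -2.33 there and -0.708 here. The authors' test was not rerun without this ant, so how far their calls rest on it was not tested.

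With the library name prefix as a further term 0 genes were called in each comparison. The 12 genes called between gamergates and transition workers kept 107.8% of their log2 fold change in the median and their sign, all 12 at an unadjusted p under 0.05. The median size of their fold change was 1.14 before and 1.36 after on the log2 scale. The 12 genes were chosen by their caste difference in these same ants, and few ants share a prefix across castes within a batch. These were 5 gamergates and 3 transition workers with b in batch B, and gamergate 12 and 4 transition workers with H in batch C. The kept fold change therefore cannot decide whether prefix or caste sets the levels of these genes. The median standard error went from 0.219 to 0.301, with a median ratio of 1.402, as it would if the prefix takes up information on caste. The calls thus ended with a wider error and not with a smaller median fold change. Such widening comes from the overlap of prefix and caste among the ants. It would arise whichever of them sets the levels, so it does not decide between them. The 3 transition workers with the prefix b had a median caste position of 0.233, from -0.201 to 0.686, and gamergate 12, the only one with the prefix H, lay at 1.40.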

How the results depend on the processing

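The fits with voom, the rRNA share, non-coding rows or both transition workers with most rRNA left out, and those without single ants were chosen only after the result was seen. For gamergates against transition workers (12 genes), transition against stable workers (1), gamergates against stable workers (26), the genes shared by both gamergate comparisons (8) and those shared with the authors' deposited table (9), in this order, the counts were as follows. Without a batch term they were 3, 1, 14, 3 and 3. With the replicate block they were 2, 0, 1, 1 and 2. With the library name prefix as a term they were 0, 0, 0, 0 and 0. With only the 2 groups compared they were 3, 1, 8, 2 and 2. In batch B alone they were 0, 0, 3, 0 and 0, and in batch C alone 0, 0, 0, 0 and 0, where fewer ants were tested. Without batch A they were 0, 1, 4, 0 and 0. With array weights they were 60, 1, 45, 18 and 24, and with voom on the recovered reads 3, 1, 5, 2 and 3. With a pseudocount of 5 the comparison with stable workers gave 17 and the shared genes 3; with one of 0.1 the shared genes were 5. Without a filter these 2 counts were 13 and 4, and with median-ratio scaling 11 and 4. Quantile normalization gave 14 genes shared with the authors' deposited table. Without transition workers 9 and 10 the first count was 23. The cause was not tested, except for the prefix term, where the tests could not tell prefix from caste. The 2 genes left with the replicate block were among the 12, and of the 60 with array weights 11 were. Same-numbered ants did not deviate together throughout (correlations of -0.280 to 0.641 over 11 pairs of gamergates and transition workers, 9 of them over 0.1, and -0.401 to 0.308 after batch was removed; 8 of 10 pairs of gamergates and stable workers and 5 of 10 of both worker groups were over 0.1; 4 of 11 gamergates matched best with their own number), so the numbers were not read as pairs.

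Without single ants the first count ran from 2 to 37, the second from 1 to 2, the third from 4 to 47, the shared genes from 2 to 16 and those shared with the authors' deposited table from 2 to 19. The first count was 2 without gamergate 6, gamergate 12 or transition worker 1, 3 without gamergate 1, 4 without gamergate 2, 5 without gamergate 7, 6 without gamergate 10, 7 without gamergate 4, 24 without gamergate 9, 26 without gamergate 11, 34 without transition worker 6 and 37 without transition worker 10. The second was 2 without gamergate 5. The third was 4 without stable worker 5, 5 without gamergate 8, gamergate 10 or stable workers 3 or 7, 6 without gamergate 4, 8 without stable worker 2, 9 without gamergate 12, 10 without gamergate 7 or stable worker 9, 12 without gamergate 5 or stable worker 10, 14 without gamergates 2 or 6, 15 without stable worker 6 or transition worker 2, 16 without gamergate 1 or transition workers 1, 3 or 4, 17 without transition worker 8 and 47 without gamergate 11. The genes shared by both gamergate comparisons were 2 without gamergates 2, 4, 6, 8, 10 or 12, stable workers 2, 5 or 7 or transition worker 1, 3 without gamergate 1 or stable workers 3 or 9, 4 without gamergate 7, stable worker 10 or transition workers 3 or 9, 5 without gamergate 3, stable worker 4 or transition workers 2, 4, 7 or 8, 14 without gamergate 11 and 16 without transition worker 10. Those shared with the authors' deposited table were 2 without gamergates 6 or 12 or transition worker 1, 3 without gamergate 1, 4 without gamergate 2, 5 without gamergate 7, 17 without gamergate 9, 18 without gamergate 11 or transition worker 6 and 19 without transition worker 10. The caste difference by batch had 0 genes in all settings run but one, and 1 without gamergate 8. No difference of a named gene that was called turned its sign in any setting. Between gamergates and transition workers, the calls of Hsal_05445 and Hsal_09095.2 held without each of the 33 ants and in 15 of 19 other settings, that of Hsal_10714 in 28 of 33 and 11 of 19, and that of Hsal_04952 in 29 of 33 and 11 of 19. The call of Hsal_09889 between worker groups held without each of the 33 ants and in 15 of 19 others. Between gamergates and stable workers the call of Hsal_04952 held without 5 of 33 ants and in 5 of 19 other settings. The alternatives on single technical runs were not run, as each ant has 1 column, nor were those on the gene lists. At these depths Hsal_10714 in workers rests on few reads, and its fold change depends on the pseudocount, from 2.51 to 5.43 between gamergates and transition workers over all settings.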

Other observations

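The test on the genes high in transition worker 10 was chosen only after the result was seen. Among 95 numbered genes high in transition worker 10, 5 neighbouring pairs had IDs at most 2 apart, against a median of 1 and a 95th percentile of 3 in 10000 random sets of tested genes of that size (p = 0.0066). Among the 67 genes of the authors' deposited table tested here, 3 such pairs were found, against a 95th percentile of 2 (p = 0.0199). The hypothesis that genes with consecutive IDs are high together may hold for the first set (5 pairs), and that genes with consecutive IDs are called together for the second (3 pairs), although the genes of 1 of these 3 pairs moved in opposite directions. Whether nearby IDs mean neighbouring or related genes was not tested.

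Sequencing batch accounted for 56.8% of the spread of the ants along the first principal component, which held 26.4% of the variance, while the group accounted for 2.91% of it. The second component held 18.3%, with 49.4% by batch and 6.70% by group. The share of rRNA reads averaged 0.637 ± 0.268% (SD, n = 4) in batch A, 0.734 ± 0.240% (SD, n = 15) in batch B and 4.14 ± 5.11% (SD, n = 14) in batch C, where it was 2.93 ± 2.42% (SD, n = 13) without transition worker 9.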
